A study of Homo sapiens with 6 samples.

How the data were processed

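Total RNA of H358 cells was extracted with TRIzol and made into stranded mRNA libraries with an Illumina kit, sequenced as paired ends, per the labels' protocols. The labels give 3 libraries with RBM47 knockdown and 3 with control knockdown. The number and the sequences of the hairpins are not given in the sources used here. The submitters' processing notes name TopHat 1.4.1, Cuffdiff 2.2.0 and the genome build hg19, without settings. The authors deposited one table of FPKM (fragments per gene, divided by transcript length and by the library's mapped fragments) for 57150 genes with Ensembl identifier, symbol and locus. How libraries were scaled to each other, and whether strand was used in the counting, is not given in the sources used here. FPKM are not counts, and no count test was run. Loci are the table's own, in hg19, and overlapping genes share one locus there (33824 distinct loci, 9700 tested genes in a shared one). The table's starts count from 0 and are printed counted from 1. FPKM of genes in shared loci, of pseudogenes and of near-identical copies are uncertain, since the assignment of shared reads is not known.

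The fragment depth per library is unknown. The relative depth was read from genes alone in their locus that lay under 0.3 FPKM in all 6 libraries and above 0 in both libraries compared. It was the most frequent ratio of their values (713 to 727 genes, 23.4 to 26.5% of them at that ratio within 0.02 on the log2 scale). Relative to RBM47 knockdown replicate 1 it was 1.03 and 1.05 in the other knockdown libraries and 1.09, 1.08 and 1.16 in control replicates 1, 2 and 3. The 10 most abundant genes held 10.7 to 12.3% of the total FPKM. Values near the floor rest on few fragments, and an FPKM of 0 says only that the gene was listed at 0.

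Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 14419 in all. The test was limma 3.58.1 (R 4.3.3) with a trended prior on log2(FPKM + 1), knockdown against control over all 6 libraries without further terms, with Benjamini-Hochberg adjusted p under 0.05. A fold change is on this scale and understates the change of low genes. Of 26 gene lists, the 24 with at least 5 tested genes were tested with camera (inter-gene correlation 0.01, Benjamini-Hochberg over the lists), and 4 lists of markers of other cell types were described. The lists cover epithelial and mesenchymal genes, splicing factors linked to EMT, RBM47 relatives, NRF2 targets and control, Wnt, p53, interferon, NF-kB, TGF-beta and ERK genes, cell cycle phases, histones, hypoxia, unfolded protein response, ATF4, sterol synthesis, lung and gastric lineages, adhesion, actin, nonsense-mediated decay, ribosomal proteins and oxidative phosphorylation. With an estimated inter-gene correlation none of the 15 lists that camera called passed (lowest adjusted p = 0.182), and 6 had an unadjusted p under 0.05. By fry, which tests whether a list's genes move one way on balance, 11 of the 15 passed.

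The groups, the test, the lists, most of the other settings and the rule for named genes were set before the data were examined. Named were RBM47, the 10 largest rises and 10 largest falls among called genes whose groups do not overlap, and in each list up to 4 called members with the largest absolute log2 fold change or, where none passed, up to 2 with the highest mean. Short RNAs, unnamed loci and symbols that occur more than once were skipped. The text gives those of each list that serve as examples, and says where another gene was added. Those other settings were pseudocounts (0.1 and 0.5), no filter or a mean of at least 5 FPKM, scaling to the same total, to the same upper quartile or by quantiles, limma without trend or with array weights, the replicate number as a block, leaving out each library, and for lists the estimated correlation and fry. Gene type, length, base composition and 3' untranslated regions came from GENCODE release 29 by Ensembl identifier, without its coordinates, which belong to another build.

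The steps were tested on simulated data of 14419 genes in the same design, with 200 genes changed by 0.5 or 1 and a further list shifted by 0.3. Of the 200 genes, 55% were recovered at a log2 change of 0.5 and 83% at 1, and the median fitted value at 1 was 1.01. Of the calls, 4% were genes neither changed nor shifted. The simulated genes varied independently, with spreads drawn from limma's own fit. A share near the threshold was therefore built in, and it does not carry over to correlated genes. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15). Splicing and transcript isoforms were not analysed here. One gene that the naming rule took is not reported here.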

Results

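The data set measured polyadenylated RNA of H358 cells, an epithelial line derived from a human non-small-cell lung cancer, after lentiviral short hairpin RNAs had lowered RBM47, an RNA-binding protein. Control cells had received a control knockdown. Each group held 3 libraries, which the series design describes as biological triplicates. The values were gene-level FPKM for 57150 genes, of which 30559 were listed at 0 in all 6 libraries. Total FPKM ran from 651951 to 673552, and 14220 to 14526 genes per library reached 1 FPKM. The number of fragments behind these values is unknown. From the smallest nonzero values, relative depth differed by a small amount, but each control library was deeper than each knockdown library. For genes at 0 or near the floor, depth thus cannot be told apart from the knockdown. With RBM47 knockdown replicate 1 set to 1, the other knockdown libraries lay at 1.03 and 1.05 and the control libraries at 1.09, 1.08 and 1.16. The series as a whole concerns alternative splicing during epithelial-to-mesenchymal transition (EMT). The comparison of the 2 groups asks which transcripts differ in level when RBM47 is lowered in an epithelial lung cancer line, and splicing itself was not analysed here.

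RBM47 was strongly reduced in every knockdown library. Its level (ENSG00000163694, in a locus on chromosome 4 from 40425272 to 40632892, hg19, that the file gives to 5 genes) was 12.01, 13.4 and 13.5 FPKM in the knockdown libraries and 85.2, 92.4 and 87.9 FPKM in the control libraries. The means were 12.9 ± 0.813 and 88.5 ± 3.64 FPKM (SD, n = 3 each), so that 14.6% of the control level was left. On the log2(FPKM + 1) scale RBM47 fell by 2.68 (SE 0.06, limma, adjusted p = 2.04e-06). The exact two-sided permutation test of 3 against 3 gave p = 0.1, the smallest value this design allows.

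Lowering RBM47 was accompanied by many changes of small size. Of 14419 genes tested, 1650 passed the threshold in limma (adjusted p under 0.05), 736 higher and 914 lower in the knockdown. Their median absolute log2 fold change was 0.365, and 51 reached an absolute value of 1, of which 41 were higher and 10 lower. In each of the 1650 genes the 3 knockdown values lay apart from the 3 control values, and so they did in 34.0% of all tested genes, where chance gives 10%. The count was lower in each fit that left out 1 library. It was 1043 without RBM47 knockdown replicate 1, 679 without replicate 2 and 1288 without replicate 3, and 876, 784 and 707 without control knockdown replicates 1, 2 and 3. Of the 1650 calls, these fits kept from 652 (without RBM47 knockdown replicate 2) to 1114 (without replicate 3), and no sign changed. A call lost in such a fit can thus follow from having fewer libraries, without a change in size.

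**Figure D1:**
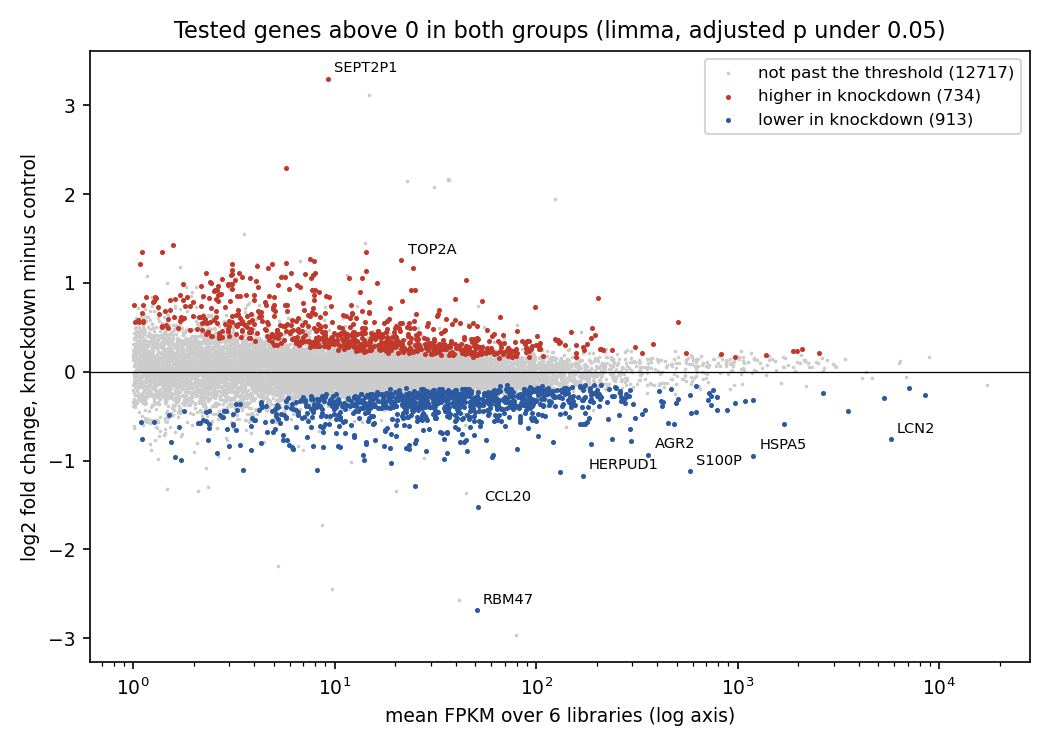
Each point is one tested gene that lay above 0 in both groups, placed by its mean FPKM over the 6 libraries (log axis) and its log2 fold change of log2(FPKM + 1), knockdown minus control. The plot shows 734 genes called higher (red) and 913 called lower (blue) by limma at an adjusted p under 0.05, most within 1 log2 unit of 0, with RBM47 at -2.68.

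Among the genes above 0 in every library, the largest rises were those of NUSAP1, ANPEP, BIRC5, TOP2A and MLF1IP. NUSAP1, a spindle protein (chromosome 15, 41624892 to 41673248), rose from 7.56 ± 1.43 to 21.0 ± 4.74 FPKM (SD, n = 3; log2 fold change 1.35, SE 0.18, limma, adjusted p = 0.00457). ANPEP, the gene of aminopeptidase N, rose from 0.353 ± 0.310 to 2.44 ± 0.753 FPKM (log2 fold change 1.35, adjusted p = 0.0105). MLF1IP, the gene of a centromere protein, had a log2 fold change of 1.25. The other 5 of the 10 largest rises that the naming rule allowed belonged to genes listed at 0 in some control libraries. A row of the repeated symbol TPD52L2, which the rule skipped, had a log2 fold change of 2.24, with 0 in each control library. SEPT2P1 was listed at 16.7, 17.3 and 16.5 FPKM in the knockdown libraries and at 4.94, 0 and 0 in the controls, and its call was lost without RBM47 knockdown replicate 2 (adjusted p = 0.0554) and without control replicates 2 (0.0524) or 3 (0.0564). RP5-1073F15.1, in a locus of 8 genes, was listed at 8.21, 8.56 and 8.12 FPKM in the knockdown libraries and at 0 in each control library. It is a processed pseudogene whose longest transcript has 170 bases, among the genes at 0 in 1 group described further on. SEPT2P1 (chromosome 1, 106240661 to 106240840) and AC007382.1 (chromosome 2, 37068327 to 37068530) lie in short loci. FPKM of such short genes can rest on few fragments. AC007382.1 and RP11-3J10.7 had log2 fold changes of 2.29 and 1.42, and a further gene, at 2.37, 2.01 and 1.65 FPKM in the knockdown libraries and at 0, 0.629 and 0 in the controls, had 1.35. The call of AC007382.1 was lost without RBM47 knockdown replicate 1 (adjusted p = 0.05), and that of RP11-3J10.7 without RBM47 knockdown replicate 2 (0.068), control replicate 1 (0.0911) or control replicate 3 (0.0863).

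Under the naming rule, which skipped short RNAs and repeated symbols, the 10 largest falls apart from RBM47 included those of secreted and calcium-binding proteins. The skipped short RNA SNORA48 had -5.49, at 0 in each knockdown library and at 168, 17.3 and 28.4 FPKM in the controls. S100P, a small calcium-binding protein (chromosome 4, 6694796 to 6698897), went from 794 ± 40.4 to 364 ± 19.9 FPKM (SD, n = 3; log2 fold change -1.12, SE 0.06, limma, adjusted p = 0.000233). HPGD, which degrades prostaglandins, MMP7, a matrix metalloproteinase, and TNFSF15, a TNF-family cytokine, had log2 fold changes of -1.11, -1.03 and -0.99 (limma, adjusted p = 0.00213, 0.00114 and 0.0022). The chemokine gene CCL20 had -1.52 (SE 0.37, adjusted p = 0.0386), with RBM47 knockdown replicate 3 at 50.1 FPKM against 17.4 and 17.8 in the other knockdown libraries. Its call was lost in 5 of the 6 fits that left out 1 library (adjusted p = 0.0969 and 0.114 without RBM47 knockdown replicates 1 and 2, and 0.0837, 0.111 and 0.0909 without control replicates 1, 2 and 3) and held without RBM47 knockdown replicate 3 (0.00305). AC017060.1 had a log2 fold change of -1.11, which passed only in the fit without control replicate 3 among those 6 (adjusted p = 0.0112, and 0.062 to 0.0932 in the other 5). RP11-443P15.2 had -0.997, with an adjusted p of 0.0511 without control replicate 3. SDF2L1, HERPUD1 and DDIT3, the remaining large falls, belong to stress-response lists described further on.

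Nearly all tested mitosis genes rose, and so did part of the DNA replication genes. Of 40 tested G2/M and mitosis genes 38 were higher in the knockdown and none lower, and 40 were higher when adjusted over the list alone. The list median was 0.978 on the log2 scale (camera, adjusted p = 6.05e-27; adjusted p = 0.182 with an estimated correlation). BIRC5, the gene of survivin, rose from 3.98 ± 0.49 to 11.1 ± 2.10 FPKM (SD, n = 3; log2 fold change 1.27, SE 0.14, limma, adjusted p = 0.00298), and TOP2A, the mitotic topoisomerase, from 12.2 ± 1.76 to 30.6 ± 4.88 FPKM (1.25, SE 0.13, adjusted p = 0.00246). NUSAP1 and the kinetochore gene CENPF (1.22) stood beside them. Of 39 G1/S and DNA replication genes 12 were higher and 1 lower, and 14 and 1 when adjusted over the list alone, with a median of 0.288 (camera, adjusted p = 1.92e-07; adjusted p = 0.182 with an estimated correlation). The ribonucleotide reductase subunit RRM2 rose by 0.98, the thymidine kinase TK1 by 0.81 and the replication factor GINS1 by 0.75, while the cyclin CCND1 fell by 0.24 on the log2 scale. TYMS, at 0.81, passed only without RBM47 knockdown replicate 1 among the fits that left out 1 library, with adjusted p = 0.0825 to 0.13 in the other 5. Of 22 replication-dependent histone genes 14 could be tested, of which 2 were higher, 2 when adjusted over the list alone (median 0.077, camera, adjusted p = 0.311). The 22 genes had a median level of 2.07 FPKM in these libraries of polyadenylated RNA. No statement on DNA replication is drawn from them. HIST1H4H (0.39) lost its call without RBM47 knockdown replicate 2 or any one of the 3 control libraries (highest adjusted p = 0.094), and HIST2H2BE (0.27) in each of the 6 fits except that without control replicate 2 (highest adjusted p = 0.108).

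Most tested genes of the unfolded protein response and of the ATF4-driven amino acid response fell. Of 29 unfolded protein response genes 21 were lower and none higher, and 25 were lower when adjusted over the list alone, with a median of -0.442 (camera, adjusted p = 1.2e-18; adjusted p = 0.182 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum (chromosome 9, 127997132 to 128003609), went from 1576 ± 200.4 to 817 ± 79.7 FPKM (SD, n = 3; log2 fold change -0.94, SE 0.10, limma, adjusted p = 0.00265). HERPUD1, which takes part in degradation of misfolded proteins, went from 236 ± 23.3 to 104 ± 10.4 FPKM (-1.17, adjusted p = 0.00107), and SDF2L1 and DNAJC3 had log2 fold changes of -1.28 and -0.89. Of 34 ATF4 and amino acid response genes 26 were lower and none higher, and 30 were lower when adjusted over the list alone, with a median of -0.373 (camera, adjusted p = 4.11e-22; adjusted p = 0.182 with an estimated correlation). They included the transcription factor DDIT3 (-1.13), the pseudokinase TRIB3 (-0.93), the cystine transporter SLC7A11 (-0.86) and the cysteine-producing enzyme CTH (-0.80).

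**Figure D2:**
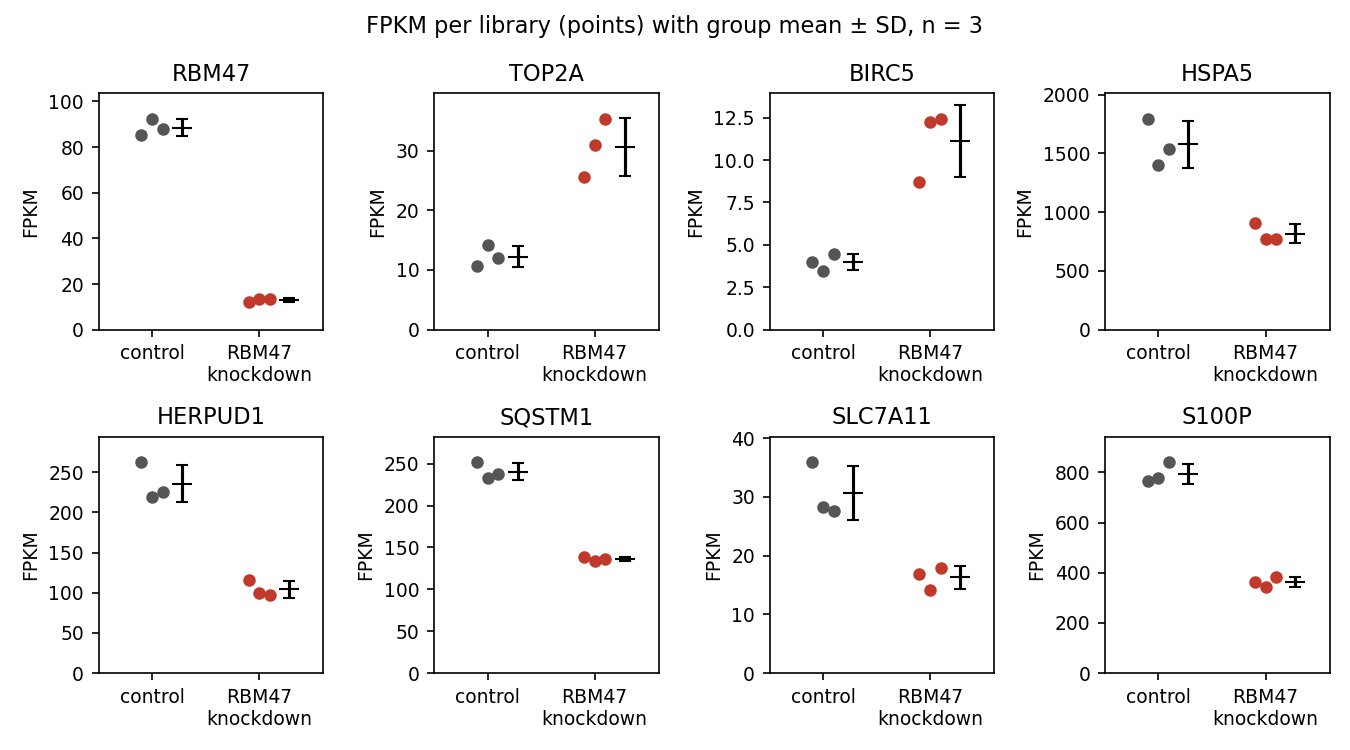
FPKM of 8 genes in each library (points; gray, control knockdown; red, RBM47 knockdown), with the group mean and SD beside them (n = 3 each) and axes that start at 0. RBM47 fell to 12.9 FPKM, TOP2A and BIRC5 were higher, and HSPA5, HERPUD1, SQSTM1, SLC7A11 and S100P were lower in each of the 3 knockdown libraries than in any control library.

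Of 31 targets of NRF2, the transcription factor of the antioxidant response, 14 were lower, none higher and 17 not past the threshold, and 18 and 1 when adjusted over the list alone, with a median of -0.217 (camera, adjusted p = 1.32e-07; adjusted p = 0.182 with an estimated correlation). SLC7A11, which the ATF4 list also holds, went from 30.6 ± 4.60 to 16.3 ± 1.93 FPKM (SD, n = 3; limma, adjusted p = 0.00534). The glutathione synthesis gene GCLC had a log2 fold change of -0.69, with adjusted p = 0.0528 without RBM47 knockdown replicate 2. OSGIN1 (-0.69) lost its call without any one of the 3 knockdown libraries or control replicate 3 (adjusted p = 0.0538 to 0.0692). AKR1C2 (-0.96) lost it without RBM47 knockdown replicates 1 or 2 or control replicates 1 or 3 (0.105 to 0.124). Of 9 genes that control NRF2, 3 were lower and none higher, and 4 and 1 when adjusted over the list alone (median -0.175, camera, adjusted p = 0.0149; adjusted p = 0.182 with an estimated correlation). The median was -0.102 without RBM47 knockdown replicate 1 and -0.109 without control replicate 1. The autophagy receptor SQSTM1 went from 240.5 ± 10.02 to 136 ± 2.15 FPKM (-0.82, SE 0.04, limma, adjusted p = 0.000318), and MAFF had -0.40. MAFG (-0.22) lost its call in each of the 6 fits without 1 library (limma, adjusted p = 0.0567 to 0.129), at log2 fold changes of -0.26 to -0.18. KEAP1, the repressor of NRF2, and NFE2L2, the gene of NRF2 itself, lay at -0.07 and -0.18 (limma, adjusted p = 0.596 and 0.0794), both named after their values were seen.

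Of 27 p53 targets 6 were lower and 1 higher, and 7 and 2 when adjusted over the list alone, with a median of -0.122 (camera, adjusted p = 0.00377; adjusted p = 0.182 with an estimated correlation). SESN2 (-0.71), which the ATF4 list also holds, BBC3 (-0.70), GDF15 (-0.59) and the cell cycle inhibitor CDKN1A (-0.48) were the largest. CDKN1A went from 76.8 ± 2.97 to 54.7 ± 3.28 FPKM (SD, n = 3; limma, adjusted p = 0.00343). The gene that rose was CCNG1 (0.32).

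Epithelial genes moved in both directions. Of 44 tested 11 were lower and 4 higher, and 13 and 5 when adjusted over the list alone, with a median of -0.077 (camera, adjusted p = 0.00902; adjusted p = 0.427 with an estimated correlation). The keratin KRT7 went from 720 ± 17.6 to 523 ± 9.73 FPKM (SD, n = 3; log2 fold change -0.46, SE 0.04, limma, adjusted p = 0.00143). The keratin KRT8 had -0.35 and the tight junction gene CLDN3 -0.42, whereas CDH3, the gene of P-cadherin, rose by 0.41. The list lost its call with quantile normalization (adjusted p = 0.0663). Of 23 mesenchymal genes 5 were higher and 1 lower, and 6 and 1 when adjusted over the list alone, with a median of 0.116 (camera, adjusted p = 0.0464; adjusted p = 0.182 with an estimated correlation). The transcription factor SNAI1 rose by 0.79, with adjusted p = 0.0532 without RBM47 knockdown replicate 2, and the lysyl oxidase LOXL2 rose by 0.50, while fibronectin (FN1) went from 191 ± 8.53 to 145 ± 5.17 FPKM (-0.40, limma, adjusted p = 0.00381). SPARC, at 0.48, lost its call in each of the 6 fits without 1 library (adjusted p = 0.0798 to 0.124). The call of the mesenchymal list was lost without RBM47 knockdown replicates 1 (0.0756) or 2 (0.0667) and without control replicates 2 (0.115) or 3 (0.0927). It was also lost with no filter (median 0.058, camera, adjusted p = 0.12), at a mean of at least 5 FPKM (0.15), with the same upper quartile (0.0531) and in limma without trend (0.0543). E-cadherin (CDH1) had a log2 fold change of -0.31 (limma, adjusted p = 0.0126) and vimentin (VIM) 0.12 (adjusted p = 0.418), both named after their values were seen.

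Transcripts of splicing factors linked to EMT were mostly not past the threshold, with 1 of 39 higher, 1 lower and the same numbers when adjusted over the list alone (median 0.034, camera, adjusted p = 0.238, and 0.0119 with quantile normalization). RBFOX2 rose from 51.9 ± 1.64 to 68.7 ± 1.14 FPKM (SD, n = 3; log2 fold change 0.40, SE 0.04, limma, adjusted p = 0.00298). ESRP1, an epithelial splicing regulator, was at 92.5 ± 1.55 against 106 ± 1.77 FPKM (-0.20, adjusted p = 0.019). Its call held only without RBM47 knockdown replicate 3 among the fits that left out 1 library, with adjusted p = 0.051 to 0.073 in the other 5. Of the RBM47 relatives and APOBEC1 cofactors 3 could be tested, too few for a list test, and none passed limma over all genes, with 1 at an unadjusted p under 0.05. HNRNPR lay at 0.04 and HNRNPAB at -0.15 (limma, adjusted p = 0.661 and 0.07), and 1 of the 3 was lower when adjusted over the list alone.

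Of 43 interferon-stimulated genes 5 were higher, none lower and 38 not past the threshold, and 8 and 0 when adjusted over the list alone, and 40 had a positive log2 fold change (median 0.249, camera, adjusted p = 6.23e-08; adjusted p = 0.436 with an estimated correlation and 0.063 by fry). RSAD2 rose from 28.29 ± 2.999 to 51.0 ± 8.32 FPKM (SD, n = 3; log2 fold change 0.82, limma, adjusted p = 0.00664), and OASL and HERC5 rose by 0.69 and 0.63. DDX60 (0.41) lost its call without RBM47 knockdown replicate 2 or control replicates 1 or 3 (adjusted p = 0.057 to 0.0659). Without RBM47 knockdown replicate 3 the list median was 0.146, and in another split of the 6 libraries it reached an absolute value of 0.287.

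Among 33 NF-kB and inflammatory genes 7 were lower and 2 higher, and 8 and 3 when adjusted over the list alone (median -0.124, camera, adjusted p = 0.0445; adjusted p = 0.58 with an estimated correlation). LCN2, the gene of lipocalin 2, went from 7222 ± 102.7 to 4281 ± 146 FPKM (SD, n = 3; log2 fold change -0.75, SE 0.05, limma, adjusted p = 0.000505), whereas the cytokine IL6 rose by 0.90. The chemokine CXCL2 (-0.91) passed only without RBM47 knockdown replicate 3 among the fits that left out 1 library (adjusted p = 0.00104, and 0.067 to 0.0877 in the other 5). The list median was -0.017 without RBM47 knockdown replicate 1 (camera, adjusted p = 0.263), -0.099 without replicate 2 (0.0768), -0.063 without control replicate 2 (0.172) and -0.219 without RBM47 knockdown replicate 3. The call was also lost with no filter (median -0.08, camera, adjusted p = 0.058), at a mean of at least 5 FPKM (0.0887), with quantile normalization (0.0709), in limma without trend (0.0543) and by fry (0.261).

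Of 36 hypoxia and glycolysis genes 9 were lower and 1 higher, and 10 and 1 when adjusted over the list alone (median -0.069, camera, adjusted p = 0.00377; adjusted p = 0.182 with an estimated correlation). NDRG1 went from 80.2 ± 1.56 to 54.3 ± 0.756 FPKM (SD, n = 3; log2 fold change -0.56, limma, adjusted p = 0.00107), and the hexokinase HK2 and BNIP3 had -0.54 and -0.40. Without RBM47 knockdown replicate 3 the median was -0.036. Of 29 ERK pathway output genes 9 were lower and none higher, and 13 and 0 when adjusted over the list alone (median -0.135, camera, adjusted p = 0.00389; adjusted p = 0.182 with an estimated correlation; -0.081 without control replicate 3). PHLDA2 (-0.50), MYC (-0.49) and JUN (-0.36) were among them. MYC and CCND1, also members of the Wnt/beta-catenin list, were the 2 of its 10 tested genes that were lower, with none higher and 3 lower when adjusted over the list alone (median -0.037, and 0.007 without RBM47 knockdown replicate 3; camera, adjusted p = 0.195, and 0.0478 by fry).

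Members of the list of TGF-beta targets had fold changes of both signs. The list does not mark which of them TGF-beta raises or lowers, so no direction of the pathway is read from it. Of 27 tested 4 were higher and 5 lower, and 5 and 7 when adjusted over the list alone, with a median of -0.037, a mean of 0.008 and a camera direction of down (adjusted p = 0.609), and the median was 0.011 with quantile normalization. ID3 rose from 16.2 ± 1.16 to 31.59 ± 2.995 FPKM (SD, n = 3; log2 fold change 0.92, limma, adjusted p = 0.00163) and ID2 by 0.79, both inhibitors of differentiation factors. Among the lower members, PDGFB had a log2 fold change of -0.60 (limma, adjusted p = 0.0174). Its call was lost without RBM47 knockdown replicate 2 or control replicates 2 or 3 (limma, adjusted p = 0.0536 to 0.0668). In the list of adhesion molecules and matrix receptors 5 of 29 were lower and 1 higher, with the same numbers when adjusted over the list alone (median -0.038, and 0.017 with quantile normalization; camera, adjusted p = 0.157). Among them ITGB2 had -0.58, LAMA3 -0.41 and LAMB1 0.36. Of 42 actin cytoskeleton genes 8 were lower and 4 higher, and 16 and 4 when adjusted over the list alone (median -0.036, and 0.011 with quantile normalization; camera, adjusted p = 0.0656), with FLNA at -0.36, ARPC5 at -0.35 and MSN at 0.35. The largest change among the called members was that of DIAPH3 (0.75), a low gene at 0.575 FPKM in the control and 1.66 FPKM in the knockdown. Its call was lost without RBM47 knockdown replicate 2 or control replicates 2 or 3 (limma, adjusted p = 0.0509 to 0.0538). The actin list passed without RBM47 knockdown replicate 3 (median -0.072, camera, adjusted p = 0.0485), without control replicate 1 (-0.055, 0.028), by fry (0.0277) and without members shared with another list (-0.068, 0.0359), a setting chosen after seeing the data. The adhesion list passed by fry (0.044), with medians of 0.011 and 0.006 without RBM47 knockdown replicate 3 and control replicate 2.

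The sterol synthesis list also holds genes of fatty acid synthesis. Of its 33 tested genes 6 were lower and 1 higher, and 6 and 4 when adjusted over the list alone (median -0.116, camera, adjusted p = 0.0822). Among the lower genes was SCD (-0.47), a fatty acid desaturase. The list passed without control replicate 1 (median -0.139, adjusted p = 0.0299) and with no filter (0.0382), and its median was -0.058 without RBM47 knockdown replicate 3. Of 20 lung epithelial lineage genes MUC5B (-0.52) and FOXA1 (-0.46) were lower and none higher, and 6 and 1 when adjusted over the list alone (median -0.048, camera, adjusted p = 0.112). The lineage list passed without control replicate 1 (median -0.115, adjusted p = 0.0313), and its median was -0.108 without RBM47 knockdown replicate 3. Only 4 of the gastric, intestinal and liver epithelial genes could be tested, too few for a list test, of which 1 was lower, also when adjusted over the list alone. This was AGR2, a secretory-pathway protein, which went from 474 ± 12.8 to 248 ± 5.71 FPKM (SD, n = 3; log2 fold change -0.93, SE 0.04, limma, adjusted p = 0.000103).

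**Figure D3:**
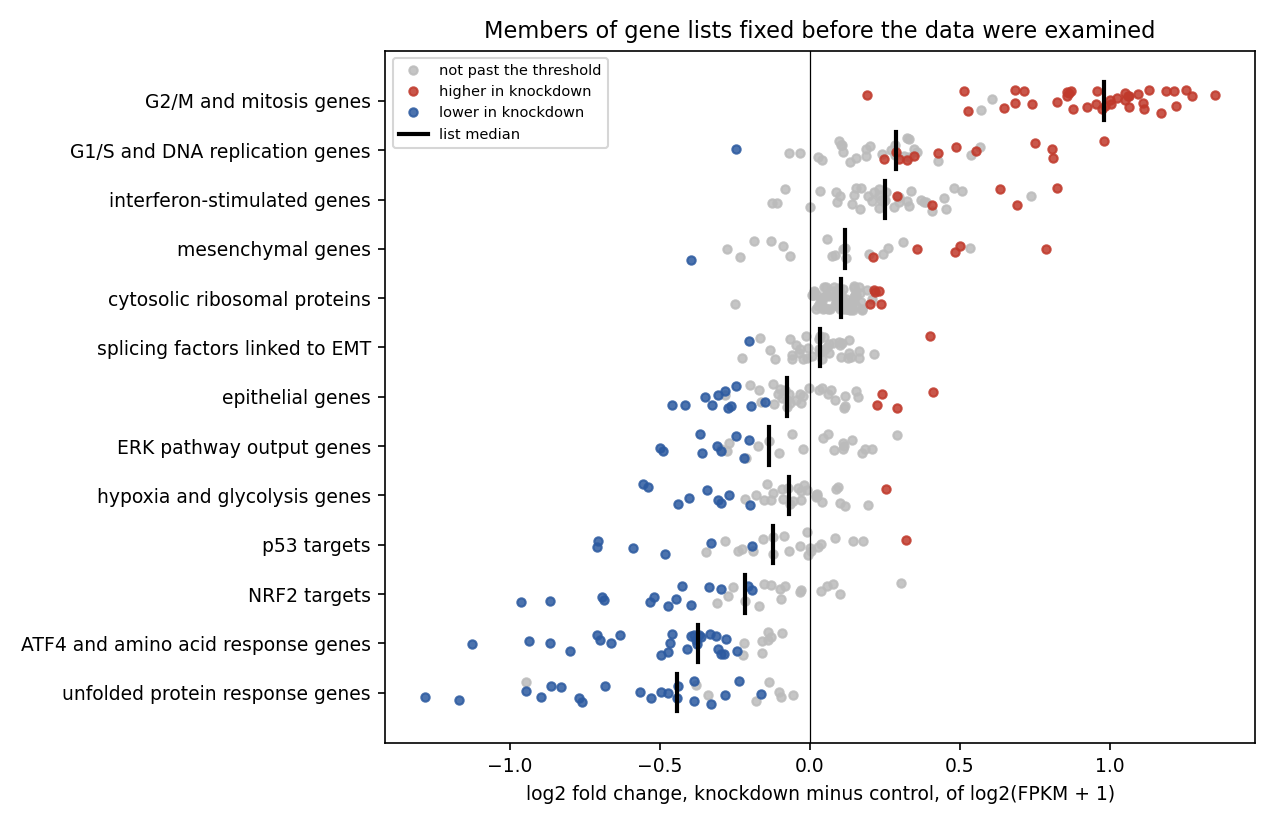
Log2 fold change (knockdown minus control, of log2(FPKM + 1)) of the tested members of 13 gene lists fixed before the data were examined; each point is a gene, red or blue where limma called it higher or lower, and the bar is the list median. The medians run from 0.978 for G2/M and mitosis genes to -0.442 for unfolded protein response genes, and epithelial and mesenchymal genes lie near 0 at -0.077 and 0.116.

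Of 68 cytosolic ribosomal protein genes 5 were higher, none when adjusted over the list alone (median 0.104, camera, adjusted p = 1.74e-07; adjusted p = 0.509 with an estimated correlation and 0.183 by fry; median 0.064 without control replicate 1). RPS24 had 0.24, with its call lost without RBM47 knockdown replicates 1 or 2 or control replicate 2 (highest adjusted p = 0.0703). RPL7 (0.23), RPSA (0.22) and RPS27 (0.21) lost their calls in each of the 6 fits without 1 library (adjusted p = 0.0556 to 0.146). Of 57 oxidative phosphorylation genes 1, NDUFA5 (-0.44), was lower, also when adjusted over the list alone. The list median was -0.032 (camera, adjusted p = 0.0452; adjusted p = 0.597 with an estimated correlation). It was 0.017 with quantile normalization, and the call was lost without RBM47 knockdown replicates 2 (0.0663) or 3 (0.212) and control replicates 2 (0.162) or 3 (0.3), with medians of -0.061 and -0.078 without RBM47 knockdown replicate 1 and control replicate 1 and of -0.017 without control replicate 3. Of 20 nonsense-mediated decay factors and targets 1 was higher (UPF3B, 0.22, adjusted p = 0.0609 to 0.13 in the 6 fits without 1 library) and 1 lower (GADD45A, -0.33, up to 0.0548 without RBM47 knockdown replicate 2 or control replicate 3), and 0 and 1 when adjusted over the list alone (median 0.054, camera, adjusted p = 0.751). Among markers of other cell types, 6 could be tested and none rose. The fibroblast markers COL1A1 and LUM were at 11.9 and 19.4 FPKM in the knockdown and 14.2 and 19.6 FPKM in the control, the endothelial marker KDR at 1.43 and 1.89, the leukocyte marker CD68 at 27.3 and 33.1, and the neuronal marker TUBB3 at 9.92 and 13.6. The leukocyte marker LCP1 was lower, at 48.1 against 59.9 FPKM (limma, adjusted p = 0.0134, n = 3 each). When adjusted over each list alone, both leukocyte markers and TUBB3 were lower. The median log2 fold changes of the tested markers were -0.127 for fibroblasts, -0.243 for endothelium, -0.293 for leukocytes and -0.424 for neurons, over 2, 1, 2 and 1 genes. The other markers lay under 1 FPKM on average.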

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

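The settings with GC and length trend removed, with protein-coding genes, with genes alone in their locus and with lists without shared members were chosen after seeing the data. RBM47 stayed past the threshold in its 18 alternatives, with log2 fold changes of -2.76 to -2.63 (limma, highest adjusted p = 0.000118; -2.71 to -2.63 without 1 library). The count of called genes, 1650 (736 higher, 914 lower), was 1301 to 2035 with the other scalings, pseudocounts, priors and corrections and at a mean of at least 5 FPKM. It was 916 (366 higher, 550 lower) with no filter, where 26591 genes were tested, and 672 (291 higher, 381 lower) for genes alone in their locus, where 4719 were tested and 598 of the 598 calls among them were kept. Without 1 library it ran from 679 to 1288 (258 to 503 higher, 421 to 785 lower), each with 5 libraries. Scaling to the same total FPKM gave 919 higher and 782 lower, with a shift of the median gene to 0.028. The 51 genes with an absolute log2 fold change of at least 1 became 121 and 89 with pseudocounts of 0.1 and 0.5, which shrink low genes less, 28 at a mean of at least 5 FPKM and 23 for genes alone in their locus (fewer genes tested), and 39 to 72 without 1 library.

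The replicate numbers were not found to pair the libraries. Deviations from the group means correlated across genes at 0.019, -0.096 and 0.077 between libraries of the same number, and 1 of the 3 numbers had its highest value with its own partner on both sides. With the replicate block, 837 genes were called (348 higher, 489 lower), 815 of them among the 1650.

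Of 24 tested lists 15 passed, 12 to 18 without 1 library and 0 with camera's estimated correlation. The directions of TGF-beta targets reversed at a mean of at least 5 FPKM (median -0.029, with camera's direction up), with quantile normalization (0.011) and in lists without shared members (0.001). Those of nonsense-mediated decay genes reversed without RBM47 knockdown replicate 1 (camera's direction down at a median of 0.036, of 0.024 to 0.075 without 1 library) and for genes alone in their locus (-0.081). So did those of lung lineage genes for genes alone in their locus (0.091) and of Wnt targets in lists without shared members (0.09). None of these lists passed there, and the cause was not tested. For genes alone in their locus the epithelial, mesenchymal and ERK lists lost their calls (camera, adjusted p = 0.202, 0.593 and 0.0784). With the GC and length trend removed the mesenchymal and NF-kB lists did (0.0544 and 0.0663), with protein-coding genes the NF-kB and oxidative phosphorylation lists (0.0567 and 0.0783), and in lists without shared members the mesenchymal and NF-kB lists (0.0951 and 0.0508). The oxidative phosphorylation list also lost its call at a mean of at least 5 FPKM (0.126), with the same total (0.0917), the same upper quartile (0.0682) and quantile normalization (0.931). So it did without trend (0.059), by fry (0.363) and for genes alone in their locus (0.219). Over all lists and settings the direction and the side of the threshold were kept 455 times, a call was lost 54 times and gained 10 times, and the direction reversed 7 times. For named genes they were kept 1539 times, a call was lost 192 times and gained 1 time, and no sign changed. The fragments behind each value are not known, so the precision that depth gives to genes near 1 FPKM cannot be stated.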

Other observations

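The test of dividing cells was chosen only after the result was seen. So were the correction for GC content and length as an alternative setting and the genes named in the next paragraph.

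Some of the clearest single-gene differences lay outside the lists. In limma 13 genes had an adjusted p under 0.001, and 5 of these stood in no list and in no set of largest changes. CNN3, the gene of an actin-binding calponin, rose from 14.8 ± 1.30 to 34.2 ± 1.32 FPKM (SD, n = 3; log2 fold change 1.16, SE 0.07, limma, adjusted p = 0.000505). IL7R, the interleukin 7 receptor, rose from 17.0 ± 0.550 to 33.0 ± 1.34 FPKM, and SPP1, the gene of osteopontin, from 146 ± 2.14 to 260 ± 14.8 FPKM (log2 fold changes 0.92 and 0.83). CYP24A1, which breaks down vitamin D, went from 154 ± 4.76 to 88.6 ± 5.79 FPKM (-0.79) and ULBP2, a ligand of a natural killer cell receptor, from 13.6 ± 0.0357 to 7.18 ± 0.168 FPKM (-0.84; limma, adjusted p = 0.000933 for both).

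Mitosis genes were higher in the knockdown. A trend with GC content and transcript length as the whole cause is argued against by the list median, which was 0.957 after that trend was removed from each library, against 0.978 before. A single library as the cause is argued against by the lowest median without 1 library, 0.882. A larger share of dividing cells in the knockdown cultures is a candidate explanation. The 39 tested G1/S genes, none of them in the mitosis list, had a median of 0.288 (quartiles 0.142 and 0.391), below the 0.978 of the mitosis list. This value was known when the test was chosen, so it is no independent support. How the cells were spread over the phases of the cycle was not measured. Whether a larger share of dividing cells would come from the loss of RBM47, from culture density at harvest or from other effects of the hairpins stays open, and an effect of RBM47 itself was not tested apart from these.

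Genes of the unfolded protein response and of ATF4 were lower in the knockdown, with a median of -0.387 over the 63 genes of both lists. After the GC and length trend was removed the median was -0.409, which argues against that trend as the whole cause. The highest median without 1 library was -0.375, which argues against a single library. A weaker stress of the knockdown cultures, through medium, density or hairpin, was not tested and stays open beside an effect of RBM47 itself.

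A small set of 55 tested genes was listed at 0 in every library of 1 group, 28 in the controls and 27 in the knockdown. They included 32 small RNAs and 12 pseudogenes, 45 were above 0 in a single library, and 3 were called. Their median longest transcript was 151 bases, against 2805.5 in 502 tested genes matched on mean FPKM (permutation p = 1e-05, the smallest that 100000 permutations can give; 89.1% of the 55 had a length). A gene at 0 in a whole group was tested only if its remaining values were high enough for a mean of at least 1 FPKM. Because FPKM are divided by transcript length, few fragments reach this mainly in short transcripts. The length difference thus follows largely from the selection and is no support. Short transcripts whose FPKM rests on few fragments stay a candidate explanation. Reads of overlapping genes given to 1 of them stay open, since 76.4% of the 55 shared a locus against 67.9% of the matched genes (Fisher's exact test, p = 0.223).

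A hypothesis that loss of RBM47 lowers transcripts with U-rich 3' untranslated regions found no backing in these values. Across 11497 genes, which are not independent replicates, the Spearman correlation of log2 fold change with the U share was 0.073, of the opposite sign to the one the hypothesis needs (permutation p = 1e-04, the smallest that 10000 permutations can give). It was 0.045 with the A share and 0.018 for the U share given GC content.

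The 6 libraries can be split into 3 and 3 in 10 ways. The real split gave the most called genes, 1650, with 4 as the highest of the others, so that 1 of 10 splits gave a result as large. It also gave the most lists past the threshold by camera with its preset correlation, 15, with 10 as the highest of the others, again 1 of 10. With 10 splits a share under 0.05 cannot be reached. Each of the other splits called 6 to 10 lists. All of them set libraries of both groups on each side, so part of the knockdown difference stays in them. The counts alone do not tell whether these calls come from that part or from differences between single libraries. A camera call thus does not by itself single out the knockdown. The rest of the difference adds to the spread within the mixed groups, so fewer called genes and smaller medians there follow largely from the mixing. Among the 15 called lists, 11 had a larger absolute median in the real split than in any other. The exceptions were the interferon-stimulated genes (0.249 against 0.287), the NF-kB genes (-0.124 against 0.231), the ribosomal protein genes (0.104 against 0.126) and the oxidative phosphorylation genes (-0.032 against 0.091). For these lists the larger medians argue against the retained part of the knockdown difference as the only source. Differences between single libraries contributed to them.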
